A study of Mus musculus with 17 samples.

How the data were processed

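WT1 ChIP-seq was made from chromatin of mice aged 7 to 8 weeks, per the labels' protocols, with the antibody sc-192. Samples were fixed with 1% formaldehyde for 5 min and chromatin was sheared to fragments of 200 to 600 bp. Glomeruli from 2 kidneys were used per immunoprecipitation. Groups were taken from the sample titles and gave 4 libraries for PBS glomeruli, 4 for ADR glomeruli, 3 for PBS podocytes, 2 for day 9 and 2 for day 14 podocytes, and 2 glomerular input libraries. The protocols speak of 3 independent experiments for the reporter mice, while 2 libraries are labelled for day 9 and 2 for day 14.

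Reads were aligned with Bowtie 0.12.7 to mm9 and peaks called with MACS2, per the submitters' processing notes. How replicates were combined, which control entered the calling, how duplicates were treated and which cutoff was set are not given in the sources used here. The authors deposited 1 narrowPeak list for each of the 5 immunoprecipitation groups, so that the libraries of a group cannot be separated and no test between groups with replicate error was possible. The fold enrichment of each peak, a ratio over the background, is the authors' value and was used to rank peaks within a list. The −log10 p and −log10 q of each peak are likewise the authors' deposited values from the caller and served as filters and ranks within a list. The integer score column deposited by the authors was read and entered no result. Start, end and summit were read from the files, and coordinates are given 1-based in mm9. Smallest −log10 q values were 1.32 and 1.31 in the glomerular lists, 1.51 and 1.52 in PBS and day 9 podocytes and 2.25 at day 14.

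Peaks were called shared when they overlapped by at least 1 bp. Each share was given in both directions with a 95% Wilson interval, beside the mean of 100 random placements of the peaks on the same chromosome, between its start and the last peak end in any list, and beside the mean share after a shift of 10 kb to either side. The 1000 strongest peaks of each list were ranked by fold enrichment. Merged regions were unions of overlapping peaks, and their counts, with the stricter q tried on them, were added after the data were seen. Windows of 100 kb counted peak summits. Library read totals were not used here. A background was read instead from the caller's values: fold enrichment was taken as the ratio of pileup plus 1 to background plus 1, and p as the Poisson tail at that background. The background given by more of the 60 strongest peaks of a list than any other value was kept, and 50, 26, 40, 43 and 36 of the 60 gave it in PBS glomeruli, ADR glomeruli, PBS podocytes, day 9 and day 14. This form is inferred, and the value holds after any scaling of libraries by the caller, so that it need not follow read depth.

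Peaks were to be assigned to genes only with an annotation of the files' build. The gene table in hand is of GRCm38 and its positions were not used, so that the occupancy of 17 fixed gene lists, the genomic location of peaks and the share of peaks with a WT1 motif were not run. The rule for named peaks for this case was the 5 strongest peaks of each list, the 5 strongest without a match in each direction of each comparison and the 5 windows with most peaks per list, and the text gives values for the leading ones. From the table, the count of protein-coding genes per chromosome (GRCm38) was used and divided by the position of the last mm9 peak end on that chromosome. The groups, comparisons, overlap rule, naming rule and 4 alternatives for each share were fixed before the data were examined. The alternatives were overlap of at least 50% of the shorter peak, summits within 200 bp, a −log10 q of at least 10 in both lists, and both lists trimmed to the length of the shorter. For the strongest peaks they were the 500 strongest and a ranking by caller p-value, and for list lengths the stricter q and merging of touching peaks.

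Correlations over chromosomes used permutation tests with 100000 resamples, two-sided, with Benjamini-Hochberg adjustment. The share expected from signal was the mean over peaks of the same one of 50 equal bins of fold enrichment. The overlap code was tested on simulated lists with known shares for each of the 5 comparisons, with 3 overlap rules, and the largest error was 0.00598 percentage points at 6694 simulated peaks for the day 14 comparisons. The background code recovered the simulated background in 10 simulated lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.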

Results

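The series profiled the genomic binding of WT1, a zinc-finger transcription factor that podocytes need, during podocyte injury in the mouse. Podocytes are the epithelial cells that cover the capillaries of the glomerulus, the filter of the kidney. WT1 was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which a region where immunoprecipitated fragments pile up above background is called a peak. Injury was induced with adriamycin (doxorubicin, ADR in the labels), a drug toxic to podocytes, and vehicle animals received phosphate-buffered saline (PBS). The 15 WT1 immunoprecipitations fell into 5 groups. Isolated glomeruli of BALB/cJ mice gave 4 PBS and 4 ADR libraries. Podocytes purified from mT/mG-Nphs2cre mice, a reporter strain in which podocytes are marked by a recombinase driven by the podocin gene promoter, gave 3 PBS libraries, 2 libraries at day 9 after ADR and 2 at day 14. The other 2 of the 17 samples were input libraries from glomeruli.

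A single peak list represented each group, so the libraries of a group could not be compared with one another and no difference between groups had a replicate check. No test between groups was run. Intervals beside shares of peaks are 95% Wilson binomial intervals, which cover the counting error of peaks and not the variation between animals. The authors' lists held 29082 peaks for PBS glomeruli, 16634 for ADR glomeruli, 23402 for PBS podocytes, 31949 for day 9 podocytes and 6694 for day 14 podocytes. The peaks covered 11.2, 5.80, 12.4, 16.1 and 2.75 Mb of the mm9 genome in the same order. With a stricter −log10 q of at least 10, the counts were 16265, 7087, 16254, 22272 and 4386. Read totals were not used here. The background pileup implied by the caller's values, after any scaling by the caller, was 1.154 reads in PBS glomeruli, 0.764 in ADR glomeruli, 2.15 in PBS podocytes, 2.022 at day 9 and 2.062 at day 14.

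A common set of WT1 sites ran through all 5 groups and held 822 to 899 of the 1000 strongest peaks of each list. Its median signal percentile was 53.7 at day 14, where it made up 70.6% of peaks, and 77.9 to 89.4 in the other lists. The peaks of all lists merged into 41766 regions. Of these, 4666 (11.2%) had a peak in all 5 lists, a number bounded by the short day 14 list, and 14400 (34.5%) in 1 list alone. With the stricter q the regions in all 5 lists numbered 2714. All 25 of the peaks named as the 5 strongest of each list had an overlapping peak in each of the 4 other lists. A site on chromosome 16 was the strongest in PBS podocytes (50786065 to 50786969, 102-fold enrichment), at day 9 (50785501 to 50786948, 137-fold) and at day 14 (50786098 to 50786779, 59.2-fold), and tied for the highest enrichment in PBS glomeruli (50786114 to 50786889, 34.8-fold). A site on chromosome 10 ranked next in all 3 podocyte lists (5165707 to 5166940 in PBS podocytes, 94.8-fold). The strongest peak of ADR glomeruli lay on chromosome 2 (27395566 to 27396210, 45.0-fold).

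The comparison of ADR with PBS glomeruli asked how WT1 binding differed in the glomerulus after injury. ADR glomeruli had fewer WT1 peaks than PBS glomeruli, 0.572 times as many, and most of the sites they had were also present in PBS glomeruli. Of the ADR peaks, 13744 (82.6%, interval 82.0 to 83.2) overlapped a PBS peak and 2890 did not. Of the PBS peaks, 13536 (46.5%, 46.0 to 47.1) overlapped an ADR peak and 15546 did not. Random placement of the peaks on their chromosomes gave 0.863% and 0.501% on average over 100 placements, and peaks moved by 10 kb to either side gave 3.37% and 1.92%.

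Strong PBS sites were among those without a peak in the shorter ADR glomerular list. Of the 1000 strongest PBS peaks, 870 had an ADR peak and 130 (13%, 11.1 to 15.2) did not, although all 1000 had an enrichment of at least 23.1-fold. Ranked by caller p-value, 91.4% of the 1000 had an ADR peak. Of the 1000 strongest ADR peaks, 993 had a PBS peak. The strongest PBS peaks without an ADR peak were at 68918578 to 68919281 on chromosome 2 (34.2-fold), 18686505 to 18687230 on chromosome 5 (31.4-fold), 27450417 to 27451033 on chromosome 18 (31.2-fold), 132502497 to 132503001 on chromosome 2 (31.0-fold) and 35579371 to 35580019 on chromosome 15 (30.6-fold). All 5 had a peak in each of the 3 podocyte lists. The strongest ADR peaks without a PBS peak were at 52065413 to 52065787 on chromosome 13 (25.7-fold), 61910626 to 61911399 on chromosome 15 (21.3-fold), 129495729 to 129496292 on chromosome 4 (20.9-fold), 156921991 to 156922327 on chromosome 1 (20.9-fold) and 169556116 to 169556473 on chromosome 2 (20.3-fold). Each of these 5 had a day 9 podocyte peak, and those on chromosomes 13, 1 and 2 had no peak in PBS podocytes. The implied backgrounds of the lists differed, with that in ADR glomeruli 0.662 times that in PBS glomeruli, where the ADR value was given by 26 of the 60 peaks used. With the stricter q the lists shrank to 16265 and 7087 peaks. With both lists trimmed to equal length by caller p-value, 59.7% of PBS peaks had an ADR peak and 61.1% of ADR peaks a PBS peak.

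The comparison of day 9 with PBS podocytes asked the same of purified podocytes early after injury. The labels give no day for PBS podocytes, and the same PBS list served the comparison with day 14. Day 9 podocytes kept most of the PBS sites and had many more, 1.37 times the number of PBS peaks. Of the PBS peaks, 20365 (87.0%, 86.6 to 87.4) overlapped a day 9 peak and 3037 did not. Of the day 9 peaks, 20436 (64.0%, 63.4 to 64.5) overlapped a PBS peak and 11513 did not. Random placement gave 1.31% and 0.965%, and the 10 kb shift gave 5.05% and 3.76%.

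Strong sites were nearly all common to PBS and day 9 podocytes. Of the 1000 strongest PBS peaks 999 had a day 9 peak, and of the 1000 strongest day 9 peaks 997 had a PBS peak. The strongest day 9 peak without a PBS peak was at 117260132 to 117260913 on chromosome 7 (50.2-fold), and its one match elsewhere was in ADR glomeruli. Next came 63195928 to 63196618 on chromosome 15 (47.6-fold) and 128703038 to 128703686 on chromosome 1 (42.5-fold), which both had peaks at day 14 and in the 2 glomerular lists, then 63026004 to 63026653 on chromosome 3 (38.0-fold) and 33290126 to 33290833 on chromosome 12 (36.5-fold). The strongest PBS peak without a day 9 peak was at 174348853 to 174349483 on chromosome 1 (27.2-fold) and had no match in any other list. Next came 73789539 to 73789987 on chromosome 7 (14.7-fold), 45992879 to 45993405 on chromosome 13 (14.3-fold) and 13636356 to 13636866 on chromosome 1 (13.98-fold), each with a PBS glomerular peak, and 58580622 to 58581083 on chromosome 13 (12.6-fold), with none. Implied backgrounds were close, at a day 9 to PBS ratio of 0.940.

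The comparisons with day 14 asked how binding stood later after injury. Day 14 podocytes had 0.286 times as many peaks as PBS podocytes and 0.210 times as many as day 9 podocytes, and nearly all of these lay at sites already present in the longer lists. Of the day 14 peaks, 6435 (96.1%, 95.6 to 96.6) overlapped a PBS peak and 6675 (99.7%, 99.6 to 99.8) a day 9 peak, which left 259 and 19 without a match. In the other direction, 6329 of the PBS peaks (27.0%, 26.5 to 27.6) and 6565 of the day 9 peaks (20.5%, 20.1 to 21.0) overlapped a day 14 peak. Random placement gave at most 1.58% in any of these 4 directions and the 10 kb shift at most 5.51%.

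The sites present at day 14 were the strong ones. Of the 1000 strongest peaks, 981 in PBS podocytes and 994 at day 9 had a day 14 peak. In the weakest decile of each list by enrichment, 0.598% of PBS peaks and 0.219% of day 9 peaks did, against 94.2% and 92.1% in the strongest decile. The strongest PBS peak without a day 14 peak was at 150555286 to 150556055 on chromosome 4 (39.4-fold), and all 5 named PBS peaks of this kind had a day 9 peak. The strongest day 9 peak without a day 14 peak was again that on chromosome 7, followed by 55232997 to 55233807 on chromosome 19 (45.5-fold) and 62250802 to 62251559 on chromosome 2 (43.0-fold). The strongest day 14 peaks without a PBS peak were at 135205239 to 135205653 on chromosome 3 (12.3-fold) and 102670021 to 102670463 on chromosome 15 (12.1-fold), both with a peak at day 9 and in ADR glomeruli and none in PBS glomeruli. The other 3 of the 5 named in this direction had peaks at day 9 and in both glomerular lists. Of all 259 such peaks, 51 had a glomerular peak with ADR alone and 44 with PBS alone. The 19 day 14 peaks without a day 9 peak had at most 5.95-fold enrichment, below the median of 6.27-fold of the day 14 list. With both lists trimmed to equal length by caller p-value, the share of PBS peaks with a day 14 peak was 71.2% and that of day 9 peaks 77.4%. The stricter q left 4386 day 14 peaks.

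**Figure D1:**
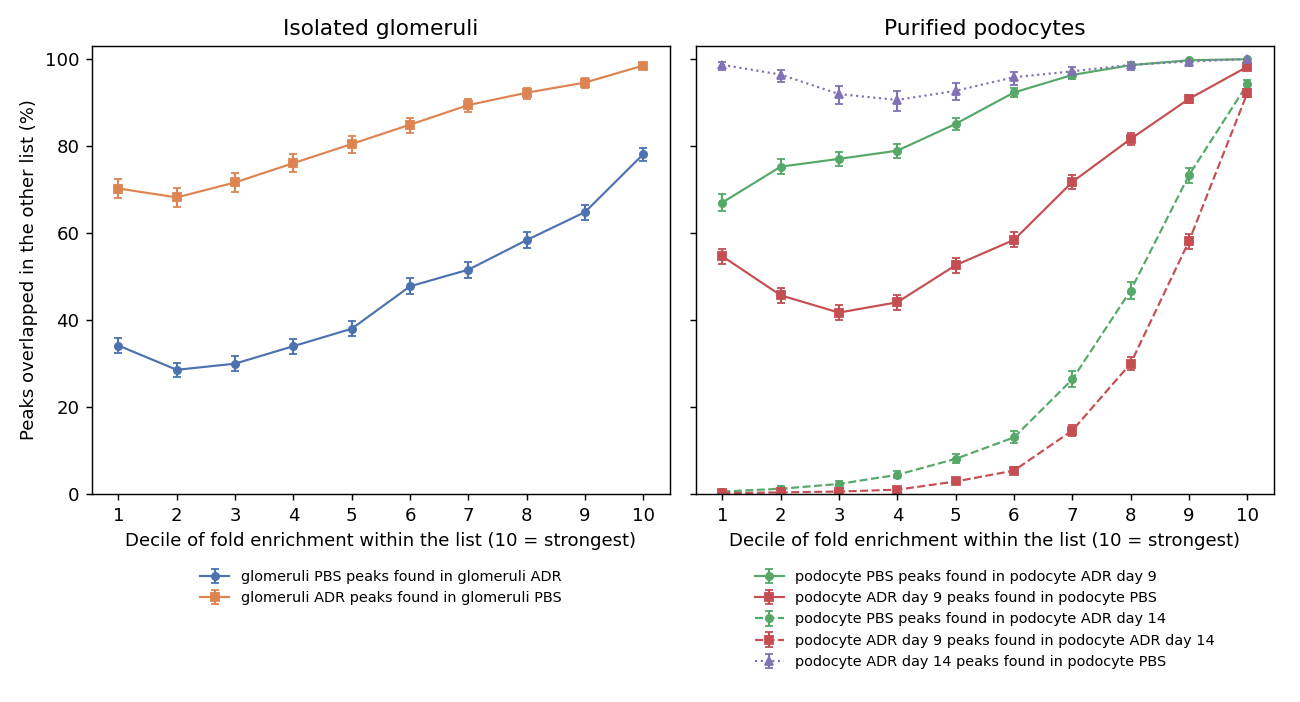
Share of peaks (%) of one list overlapped by a peak of another, by decile of fold enrichment within the list (10 = strongest), for isolated glomeruli and purified podocytes; points are shares and bars 95% Wilson intervals. The share of day 9 peaks with a day 14 peak runs from 0.219% in the weakest decile to 92.1% in the strongest. That of PBS glomerular peaks with an ADR peak is 34.1% in the weakest decile, lowest at 28.6% in decile 2, and 78.1% in the strongest.

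Across the 3 podocyte lists, peaks merged into 34687 regions. Regions in PBS and day 9 but not day 14 formed the largest class, with 13824 (39.9%, 39.3 to 40.4). Regions in day 9 alone followed with 11266 (32.5%, 32.0 to 33.0), then those in all 3 lists with 6304 (18.2%, 17.8 to 18.6) and those in PBS alone with 3030 (8.74%, 8.44 to 9.04). Regions in day 9 and day 14 numbered 245, those in day 14 alone 12 and those in PBS and day 14 alone 6. With the stricter q these last 4 classes held 1861, 98, 2 and 2 regions.

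**Figure D2:**
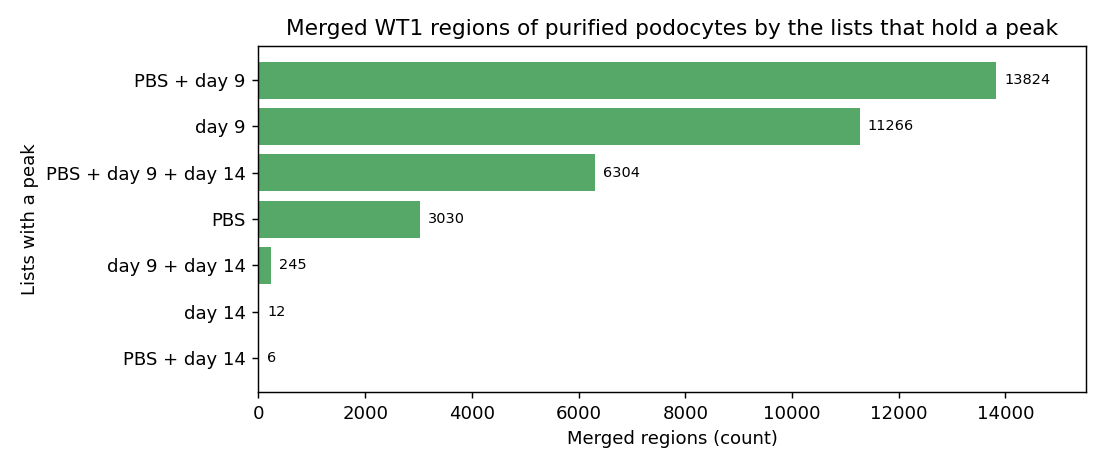
Number of merged WT1 regions of purified podocytes (horizontal axis, count) for each combination of the PBS, day 9 and day 14 lists that hold a peak (vertical axis). Of 34687 regions, 13824 are in PBS and day 9 alone and 12 in day 14 alone.

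The comparison of PBS podocytes with PBS glomeruli set binding in the purified cell against that in the whole glomerulus, with strain and tissue preparation differing together. Most sites were common to both. Of the podocyte peaks 18877 (80.7%, 80.2 to 81.2) overlapped a glomerular peak, and of the glomerular peaks 19306 (66.4%, 65.8 to 66.9) overlapped a podocyte peak, against 1.05% and 0.859% at random and 3.98% and 3.25% after the 10 kb shift. Of the 1000 strongest peaks, 986 of the podocyte list and 990 of the glomerular list had a match. The strongest podocyte peaks without a glomerular PBS peak were at 80668748 to 80670276 on chromosome 7 (47.2-fold), 12154344 to 12155088 on chromosome 18 (42.5-fold) and 70299100 to 70299702 on the X chromosome (38.5-fold), and all 5 peaks named in this direction had day 9 and day 14 peaks. The strongest glomerular peaks without a PBS podocyte peak were at 123488881 to 123489486 on chromosome 3 (34.3-fold) and 119381890 to 119382622 on chromosome 6 (28.1-fold), both with ADR glomerular and day 9 podocyte peaks. The implied background of the glomerular list was 0.537 times that of the podocyte list.

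WT1 peaks gathered in dense windows, several of which recurred between groups. The window at 98600001 to 98700000 on chromosome 11 held the most peaks in PBS glomeruli (24), PBS podocytes (20) and day 14 podocytes (9), with 19 at day 9 and 11 in ADR glomeruli. In ADR glomeruli the densest window was at 167600001 to 167700000 on chromosome 2, with 20 peaks against 16 in PBS glomeruli, 9 in PBS podocytes, 17 at day 9 and 0 at day 14. At day 9 it was at 34900001 to 35000000 on chromosome 8, with 23 peaks against 12 in PBS podocytes and 8 at day 14. The window at 60700001 to 60800000 on chromosome 2 held 22 peaks at day 9, 9 in PBS podocytes and 2 at day 14. The window at 132600001 to 132700000 on chromosome 4 held 21 peaks in PBS glomeruli and 19 in ADR glomeruli, and that at 79600001 to 79700000 on chromosome 10 held 19 and 18. The window at 7200001 to 7300000 on chromosome 19 held 20 and 5.

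**Figure D3:**
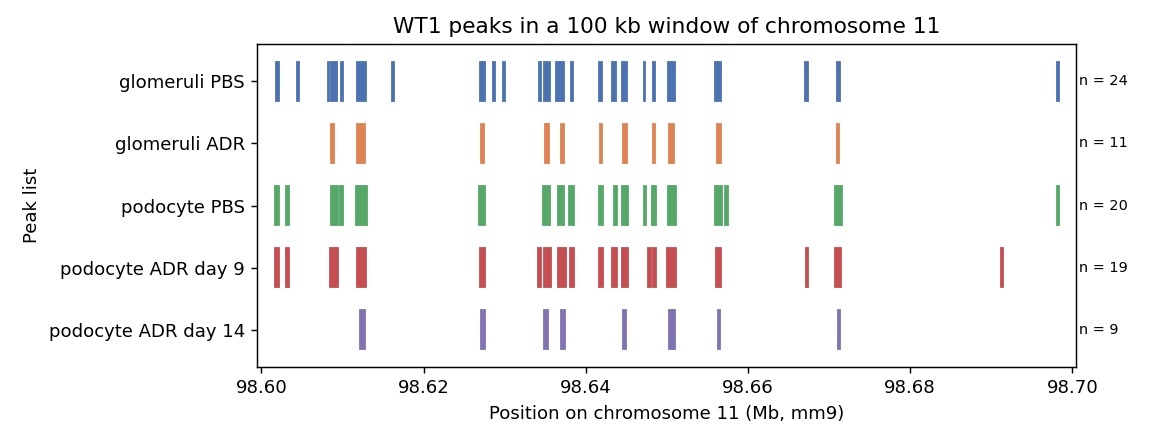
WT1 peaks of the 5 lists in the window at 98600001 to 98700000 of chromosome 11 (horizontal axis, position in Mb, mm9); each block is a peak drawn to scale and each line a list, with the number of peaks at the right. PBS glomeruli have 24 peaks there and day 14 podocytes 9.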

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

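The shares of the 1000 strongest peaks and the counts at a stricter q were planned, but their use to weigh explanations and the other tests in this part were chosen after the results were seen. The exception is the test of strong glomerular sites for a day 9 podocyte peak, and there the reading of its interval was set after its value was known.

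The number of peaks after ADR was 0.572 times the PBS number in glomeruli and 1.37 times in podocytes at day 9, opposite directions, while at day 14 it was 0.286 times in podocytes. The implied background of ADR glomeruli was 0.662 times that of PBS glomeruli, and the labels give no day for glomeruli or PBS podocytes. With 1 list per group the difference in direction was not tested.

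The day 14 podocyte list was far shorter than the day 9 list. A difference in cutoff leaves the gap, with 4386 against 22272 peaks at a −log10 q of at least 10. Day 9 signal separated the peaks found at day 14 from those not found with an area under the curve of 0.940, as weaker enrichment across all sites would, and a lower depth may give the same. Depth stays open, since the ratio of implied backgrounds, day 14 over day 9, of 1.02 holds after scaling by the caller and read totals were not used here. Weaker enrichment in turn may come from less WT1 on chromatin or a less efficient immunoprecipitation of these 2 libraries, and no value measured here separates these.

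Among the 1000 strongest PBS glomerular peaks, 13% had no ADR peak, while 91.4% had one when ranked by caller p-value. Recovery over all PBS peaks, less that expected from their signal, rose with the gene density of the autosome (Spearman's rho 0.842, permutation test, adjusted p = 0.00032). This was tested first. A test on the strong peaks themselves was put in its place after that result was seen. There, kept and missing autosomal peaks differed by -0.0564 genes per Mb (SE 0.221) in the mean gene density of their autosomes, a different measure from the first. No large difference in gene density was thus seen among the strong peaks, but a small one stays open. Loss of the same sites in injured podocytes was weighed next. At day 9, 99.4% of kept and 97.7% of missing sites had a peak. The difference was 1.73 percentage points (0.0322 to 6.003) in a share close to its ceiling. In PBS podocytes the shares were already 99.2% and 97.7%, and 127 of the 130 missing sites had a peak in either list. No drop in peaks from PBS to day 9 was thus seen at the missing sites. A weakening that leaves a peak was not tested. Of the 127 PBS podocyte peaks at the missing sites, 74.8% had a day 14 peak against 86.7% expected from their PBS podocyte signal, a difference of -11.9 points (-20.1 to -5.18), and the kept sites were 6.77 points above expectation. A candidate explanation is a WT1 site class that weakens after injury in both models. Sites of lower true strength than their PBS peak shows could be missing from both short lists and stay open too. So does a lower depth of the ADR list acting with them. Depth alone would remove weak peaks first. Yet 34.1% of PBS peaks in the weakest decile had an ADR peak, and PBS signal separated peaks found in ADR glomeruli from those not found with an area under the curve of 0.673. The weakest decile was not the least recovered, however, with 28.6% in decile 2, so fold enrichment need not order peaks by how easily they are detected. No lower depth was simulated and no replicate check was possible. These values therefore do not decide whether depth alone left out the strong peaks.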

How the results depend on the processing

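No paired analysis was possible because each group is represented by 1 peak list, and for the same reason no replicate could be left out. Not run, for want of an annotation or genome of the files' build, were gene list occupancy, genomic location and WT1 motif share with their 6 alternatives. Shares are given below in the order PBS in ADR and ADR in PBS for glomeruli, PBS in day 9 and back, PBS in day 14 and back, day 9 in day 14 and back, and PBS podocytes in PBS glomeruli and back. With a −log10 q of at least 10 in both lists they were 36.6, 84.6, 88.5, 65.0, 26.1, 97.7, 19.5, 99.9, 73.5 and 74.3%, and the cause was not tested. With both lists trimmed to equal length they were 59.7, 61.1, 76.4, 76.1, 71.2, 72.7, 77.4, 79.0, 72.9 and 73.9%, so that the 5 shares of the longer lists, whose weak peaks were no longer counted, were higher and the 5 shares of the shorter lists, whose weak partners were removed, lower. With summits within 200 bp, 8 shares left their interval (45.1, 78.9, 84.1, 61.6, 93.3 for day 14 in PBS, 97.0 for day 14 in day 9, 77.7 and 62.5%), and with 50% of the shorter peak covered 2 did (79.97 and 65.8% for podocytes and glomeruli). The rule of 50% is stricter by construction. The summit rule does not require overlap, and the cause of its lower shares was not tested. Without chromosomes X, Y and M, an alternative chosen after seeing the data, all 10 shares stayed in their intervals. For the 500 strongest peaks, 6 shares moved, to 89.8% (PBS in ADR glomeruli), 99.8% (ADR in PBS glomeruli), 100% (PBS in day 9), 99.8% (PBS in day 14), 100% (day 14 in PBS) and 99.8% (day 9 in day 14). Ranked by caller p-value, 4 moved, to 91.4% (PBS in ADR glomeruli), 100% (PBS in day 9), 99.6% (PBS in day 14) and 100% (day 14 in PBS). The cause of these was not tested. List lengths at the stricter q moved by over 1.5 times in PBS glomeruli (16265), ADR glomeruli (7087) and day 14 podocytes (4386), which follows from the filter, and merging touching peaks changed none of the 5. Read totals were not used here, and how depth limits weak peaks was not tested.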

Other observations

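The tests and alternatives in this part were chosen after the results were seen; for the odds ratio by strength of the glomerular peaks, chosen after the odds ratio itself, what each outcome would mean was written before its own values were seen. The peaks named here by coordinates on chromosome Y were chosen after their values were seen.

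Glomerular peaks seen after ADR alone favoured day 9 over PBS podocytes more than glomerular peaks seen with PBS alone did, among those with a match in just one of these podocyte lists. Of the 2890 ADR glomerular peaks without a PBS glomerular peak, 46.2% had a day 9 podocyte peak and 21.5% a PBS podocyte peak. Of the 15546 PBS glomerular peaks without an ADR peak, these shares were 64.8% and 52.9%. Among peaks with a match in just one of the 2 podocyte lists, 859 to 145 ADR-only sites and 2716 to 859 PBS-only sites matched day 9, an odds ratio of 1.87 (95% interval 1.55 to 2.27, peaks taken as independent).

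A candidate explanation is a set of sites that WT1 occupies after injury in both models, which was not tested apart from the odds ratio itself, and other causes that act on whole lists stay open. Scatter of peaks near the calling threshold would bring the ratio near 1 among strong peaks. It was 2.39 (1.80 to 3.16) in the stronger part of the glomerular peaks and 1.39 (1.06 to 1.81) in the weaker part. Each set was split at its own median, 5.86-fold for ADR-only and 6.45-fold for PBS-only peaks. These medians lie at percentiles 28.9 and 39.0 of their lists, so the stronger part need not be strong within its list. Podocyte signal was not split, so the split cannot exclude scatter near the podocyte thresholds. The odds ratio was 1.89 with a −log10 q of at least 10, 1.87 without chromosomes X, Y and M and 13.9 with day 14 in place of day 9, where 51 and 44 sites carry the ratio. Strain and preparation differ between the models and the day of the glomeruli is not given in the labels, and this stays a hypothesis from 1 list per group.

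The share of PBS glomerular peaks with an ADR peak, less the share expected from their signal, rose with the gene density of the autosome. Over 19 autosomes Spearman's rho was 0.842 (permutation p = 4e-05, adjusted 0.00032 over 8 relations) and Pearson's r was 0.851 (p = 2e-05, the smallest the permutations can give, adjusted 0.00016), and r was 0.708 without the 2 autosomes farthest from the median density. Autosomes share one pair of lists and are not replicates. This difference ran from -4.42 points on chromosome 13 to 5.09 points on chromosome 7. Among the 1000 strongest PBS peaks alone no such relation was detected: autosomes of kept peaks averaged 8.55 and those of missing peaks 8.60 genes per Mb (permutation p = 0.79). With an SE of 0.221 genes per Mb for the difference, a small relation among these stays open. On the X chromosome 37.3% (33.5 to 41.2) of 601 peaks were found against 46.7% expected. That is -9.38 points, where the line through the autosomes gave -2.87 points at the gene density of X, so X lay off the line. In the reverse direction 92.7% (88.8 to 95.3) of 247 ADR X peaks had a PBS peak against 84.0% expected. This difference of 8.71 points lay outside the autosomal range of -1.80 to 1.40, and the cause was not tested. For the relation with gene density over autosomes, none of the 7 other directions within a model passed an adjusted p of 0.05, the nearest being day 9 peaks in PBS podocytes (r = 0.572, p = 0.016, adjusted 0.064, permutation tests).

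Peaks lay close together in every list. A neighbour within 10 kb was found for 56.9% of PBS and 45.5% of ADR glomerular peaks and for 51.3%, 60.01% and 28.7% of PBS, day 9 and day 14 podocyte peaks, against 20.9, 12.8, 17.2, 22.5 and 5.23% with random placement. Thinned at random to the 6694 peaks of day 14, the other lists gave 21.4% (PBS glomeruli), 24.4% (ADR glomeruli), 21.6% (PBS podocytes) and 21.9% (day 9), with SD from 0.636 to 0.689 over 100 draws.

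Peaks on the Y chromosome numbered 22 in PBS podocytes, 25 at day 9, 1 in PBS glomeruli and 0 in ADR glomeruli and at day 14. The strongest at day 9 (145406 to 146109) had 31.1-fold enrichment, and of the 200 autosomal day 9 peaks nearest to it in signal 95% (91.0 to 97.3) had a day 14 peak, while 1.10 Y peaks in all were expected at day 14 at the autosomal rate. The same site had 25.7-fold enrichment in PBS podocytes and 13.9-fold in PBS glomeruli. Of the 19 day 14 peaks without a day 9 peak, 7 lay on X, in 4 of 15 loci joined within 50 kb, and 10 of 10000 random draws of weak day 14 loci held as many X loci. In the day 9 list 21.8% (18.8 to 25.1) of X peaks had a day 14 peak against 21.4% expected from their signal. Of the day 14 X peaks, 95.4% (90.9 to 97.8) had a day 9 peak against 99.8% expected and 90.2% (84.5 to 94.0) a PBS podocyte peak against 95.6% expected. Sex of the animals did not enter the groups used here. Whether it differed between groups was not tested, so these X and Y peaks cannot be read as an effect of injury. The mitochondrial genome held 6 peaks in PBS podocytes, 6 at day 9, 3 at day 14 and 0 in both glomerular lists.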
